A study of Glycine max with 2 samples.

How the data were processed

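Small RNA was sequenced from mature soybean seed, stored in the dark at 12 °C, and from germinating seed kept in a greenhouse at 26 °C, with a 12 h photoperiod after an initial dark period and collections at days 3, 5 and 7. Per the labels' protocols, the RNA of the 3 germinating stages was mixed in equal amounts into 1 library, RNA of 20 to 30 nt was taken from an acrylamide gel, adapters were ligated at both ends, and the cDNA was amplified by PCR before Illumina GAII sequencing. The deposited values are counts, the number of reads of each distinct sequence, with no normalization. The trimming tool, filters, aligner and genome build are not given in the sources used here, and the deposited counts carry no genome position.

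Each file listed only sequences of 19 to 24 nt, so its total is part of a library and not the library's full depth, and the full totals are not given in the sources used here. All shares and RPM values (reads scaled to a common total) are therefore relative to the listed reads. A row with a blank sequence and 1 read in each file was left out. Sequences with an undetermined base held 1.14% of reads in both libraries, 99.1% of them at the first base, and were kept. Sequences with 1 read made up 84.1% of distinct sequences in mature seed and 88.5% in germinating seed, and the 10 leading sequences held 21.2% and 20.1% of reads. A count of 0 allowed up to 3 counts, which is 0.988 RPM in mature seed and 1.15 RPM in germinating seed.

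Reads were assigned to 36 microRNA families and to tasiARF with a list of mature sequences. A sequence belonged to a family when it held positions 2 to 17 of a reference with at most 1 substitution, starting at its position 1 to 5. Ties went to fewer substitutions and then to the family listed first, so closely related families such as miR159 and miR319 may exchange some reads. Of the 36 families, 35 matched names among the 659 microRNA genes in the reference gene table of the assembly Glycine_max_v4.0, which served for names only. No coordinates are given, since the counts name no build. The families, the 8 family lists and the 11 animal microRNAs (matched over 20 bases) were fixed before the data were examined, as were the design and the alternatives except those named in the closing section as chosen later. The ribosomal RNA list (5S, 5.8S and the 25S 3′ region, matched on both strands with at most 1 substitution), the list of 19 transfer RNA 5′ ends (exact matches) and the list of other hairpin arms for 20 families were written after the data had been examined. All of these sequences were written from general knowledge and not from a database.

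Ratios were computed on reads scaled to all listed reads of a library, germinating over mature seed, with exact conditional (Clopper-Pearson) 95% intervals, and shares with exact Clopper-Pearson 95% intervals. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A family was called higher or lower when it had at least 50 reads over both libraries, a ratio of at least 2-fold and an interval that excluded 1. Each group was 1 library, so no test across replicates was possible, no p-values are given and no replicate could be left out. For each family list the median log2 ratio was set against 10000 random lists of the same size, drawn for each member from the 50 sequences of 20 to 22 nt outside the families nearest in mean RPM, with 0.5 added to the counts of the random sequences. The text names the 5 families with most reads in each library, up to 10 called families in each direction with the largest ratios, any member of a family list, and the 5 sequences outside the families with most reads in each library; the further sequences in the closing section were chosen after their values were seen. A stretch of ribosomal sequence was joined from overlapping reads by words of 16 bases.

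The calls were tested on simulated data, with Poisson counts drawn for the 7086 sequences with at least 50 reads in the comparison of germinating over mature seed. With a simulated 3-fold rise 100% of 50 sequences were called higher, and with an 8-fold rise 100% of 50. At 0.333-fold 97.3% of the 37 sequences that kept the minimum number of reads were called lower, and 13 fell under it. At 0.125-fold 100% of 27 were called lower and 23 fell under the minimum. Of 6497 unchanged sequences 0.369% were called. The simulation held counting error only, so this rate does not cover variation between libraries. In the assignment, 99.7% of 880 references with 1 substitution went to their own family, and none of 20000 random sequences was assigned.

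The alternatives covered the scaling of the libraries, the substitutions allowed, the minimum number of reads, sequences with 1 read, leading sequences, equal depth, and distinct sequences in place of reads. Genome matches, annotation classes and hairpin candidates need a genome and were not analysed here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.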

Results

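Small RNAs were sequenced from soybean (Glycine max) seed of the cultivar Conquista in 2 libraries, 1 from mature seed and 1 from a pool of germinating seed that combined equal amounts of RNA from days 3, 5 and 7. The mature seed library held 3035193 reads of 707906 distinct sequences, and the germinating seed library held 2603982 reads of 917601 distinct sequences, all of 19 to 24 nt. With 1 library per group there was no replicate check, no test was run and no p-value is given. Each ratio below compares these libraries, not the conditions, and its exact 95% interval covers counting error only. "Rose" and "fell" are used only where a ratio of RPM (reads scaled to a common library total) was at least 2-fold, its interval excluded 1 and at least 50 reads were counted over both libraries.

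The first comparison asked which microRNA families differed in abundance between mature and germinating seed. The families miR403, miR164, miR408, miR396, miR1508 and miR171 rose in germinating seed, and miR3522 and miR395 fell. The family miR403, which targets an Argonaute gene, rose 6.99-fold (interval 3.86 to 13.7, from 13 to 78 reads). The family miR164, which targets NAC transcription factor genes, rose 5.46-fold (3.97 to 7.64, from 47 to 220 reads), and miR396, which targets growth-regulating factor genes, rose 3.21-fold (2.97 to 3.47, from 899 to 2474 reads). The family miR3522 was 2.28-fold lower in germinating seed (2.22 to 2.35, from 16486 to 6200 reads), and miR395, which targets genes of sulfate assimilation, was 2.22-fold lower (1.92 to 2.57, from 674 to 261 reads).

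The other families that rose were less deeply counted or closer to the threshold. The family miR408, which targets genes of copper proteins, rose 3.50-fold on 13 and 39 reads (1.83 to 7.14). The legume family miR1508 rose 2.66-fold (2.07 to 3.44) on 92 and 210 reads. The family miR171, which targets GRAS transcription factor genes, rose 2.27-fold (1.99 to 2.58) on 354 and 688 reads. The lower bounds for miR408, miR171 and miR395 lay under 2-fold. The log2 ratio of miR171 dropped below 2-fold with 2 substitutions allowed (0.81) and without the leading sequence of each family (0.53), and that of miR1508 when only sequences equal to a reference over its first 20 bases counted (0.86). That last setting also left miR403 without reads and miR408 under the minimum. Over distinct sequences with at least 2 reads none of the 8 families was called. There the log2 ratios of all 8 were smaller in size. Those of miR164 (2.09), miR408 (1.41), miR1508 (1.09) and miR403 (1.09, from 2.81) were still at least 2-fold but had intervals that included 0, and those of miR171 (0.09), miR396 (0.85), miR395 (-0.74) and miR3522 (-0.76) were under 2-fold. The families miR164, miR403 and miR408 were under the minimum without their leading sequences.

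Of 36 families with reads, 27 had at least 50 reads, and among these 6 rose, 2 fell and 19 did neither. By the same rule, 458 of the 7086 single sequences with at least 50 reads were called higher in germinating seed and 2281 lower. The family miR1510 had a ratio of 1.98 (1.88 to 2.09), miR390 a ratio of 1.88 (1.45 to 2.44) and miR482/miR2118 a ratio of 1.59 (1.53 to 1.66). At the other end, miR162 had a ratio of 0.570 (0.525 to 0.619) and miR398 a ratio of 0.585 (0.467 to 0.730). The 9 families under the minimum were miR172, miR393, miR394, miR397, miR399, miR530, miR827, miR828 and miR2119. Among them miR172, which targets genes of the AP2 class, had 5 reads in mature and 17 in germinating seed (ratio 3.96, interval 1.40 to 13.7). The families miR2119, miR530, miR827 and miR828 had no read in mature seed, which allows up to 0.988 RPM, and 4, 1, 1 and 1 reads in germinating seed.

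The median log2 ratio of the 11953 sequences with at least 10 reads in both libraries was -0.36, so the scaling of the libraries bears on every direction given here. Relative to that median, 9 families rose and none fell, against 6 and 2 scaled to all reads. The families miR390, miR482/miR2118 and miR1510 joined those that rose, while miR395 and miR3522 kept negative log2 ratios of -0.78 and -0.83 without reaching 2-fold. On that scale the log2 ratios of miR159, miR167, miR168, miR319, miR1507 and miR2109 changed from negative to positive, to 0.15, 0.06, 0.07, 0.04, 0.22 and 0.33. The median differed by length: -0.18 for 21 nt and -0.22 for 22 nt, but -0.80, -0.66, -0.78 and -0.60 for 19, 20, 23 and 24 nt. Below the 21-nt median lay miR159 (-0.22), miR167 (-0.31), miR168 (-0.29) and miR319 (-0.33), so their change of sign depends on the lengths included.

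**Figure D1:**
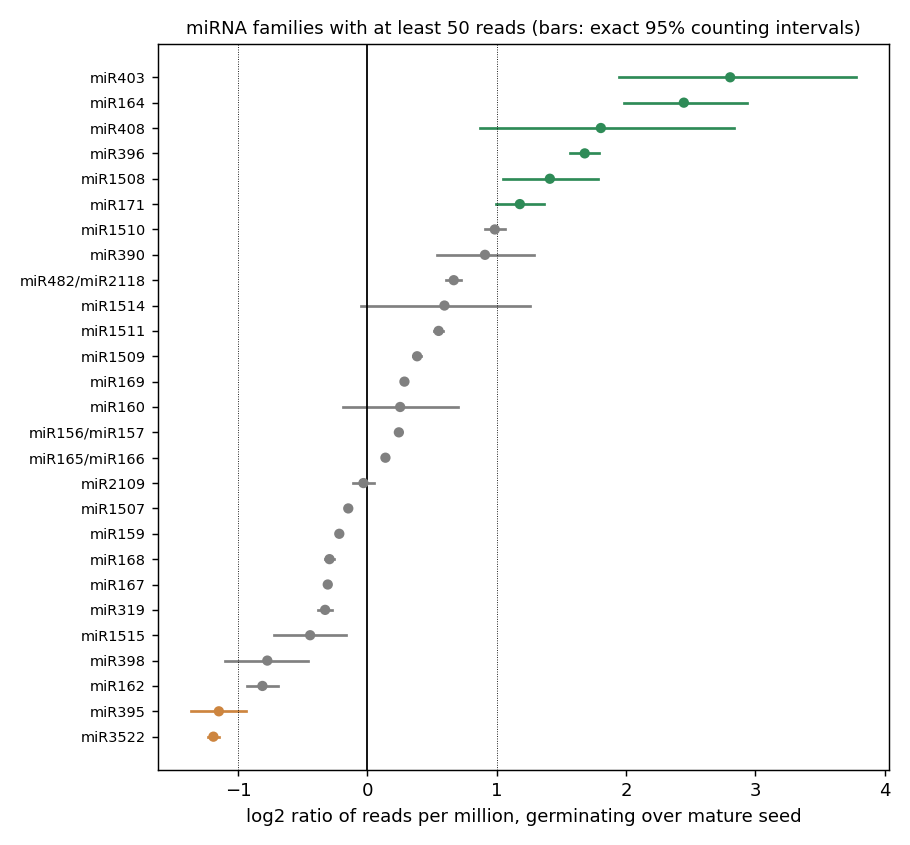
Log2 ratio of RPM in germinating over mature seed (x axis) for the 27 miRNA families with at least 50 reads (y axis), 1 library per group; points are ratios, lines are exact 95% counting intervals, dotted lines mark 2-fold. The families drawn in green rose, from miR171 at 1.18 to miR403 at 2.81, and those in brown, miR395 at -1.15 and miR3522 at -1.19, fell; scaled to the median sequence, neither of these last 2 families passed 2-fold, and miR159, miR167, miR168, miR319, miR1507 and miR2109 crossed to the positive side.

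The same 5 families held most microRNA reads in both libraries: miR159, miR165/miR166, miR167, miR169 and miR156/miR157. Together they made up 78.7% of microRNA reads in mature seed and 78.4% in germinating seed. The family miR159, which targets MYB transcription factor genes, led with 240724 reads in mature and 177753 in germinating seed, or 37.3% and 33.0% of microRNA reads (ratio 0.861, interval 0.855 to 0.866). Its main sequence, TTTGGATTGAAGGGAGCTCTA, was the most abundant sequence of each library, with 6.94% and 5.94% of all reads. The family miR165/miR166, which targets HD-ZIP transcription factor genes, had 74521 and 70464 reads (ratio 1.10, interval 1.09 to 1.11). The auxin-related family miR167 had a ratio of 0.809 (0.800 to 0.818), positive in log2 once scaled to the median sequence. The family miR169, which targets NF-Y genes, had a ratio of 1.22 (1.21 to 1.23), and miR156/miR157, which targets SPL genes, a ratio of 1.18 (1.17 to 1.20).

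MicroRNA families as a whole made up 21.3% of reads in mature seed (21.2 to 21.3%) and 20.7% in germinating seed (20.7 to 20.8%). The order of the libraries turned when sequences with 1 read were left out, with 26.4% in mature and 30.0% in germinating seed.

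By function, the regulators of developmental transcription factors had 8 measured families of 10, of which 3 rose, none fell and 5 did neither. Those that rose were miR164, miR171 and miR396, and the rest of the measured members were miR156/miR157, miR159, miR165/miR166, miR169 and miR319. Their median log2 ratio was 0.27, above 88.8% of 10000 random lists of sequences of 20 to 22 nt nearest in abundance, whose own median was -0.34, as a description of these libraries. The most abundant families had no close match in abundance. The leading sequence outside the families had 34311 RPM in mature and 21790 in germinating seed, against 79311 and 68262 for miR159. Among the families of disease resistance gene regulators of 22 nt, all 4 were measured and none passed 2-fold, although the leading sequence of miR2109 was of 21 nt in these libraries. Here miR1510 and miR482/miR2118 lay above 1, and both passed 2-fold once scaled to the median sequence (log2 ratios of 1.35 and 1.03). In turn miR1507 had a ratio of 0.903 (0.892 to 0.915) and miR2109 a ratio of 0.980 (0.925 to 1.04), both above 1 once scaled to the median sequence. The median of this list was 0.32, above 76.6% of random lists. The other legume families had 6 measured members of 7, with miR1508 higher, miR3522 lower and miR1509, miR1511, miR1514 and miR1515 in neither class. Their median log2 ratio of 0.47 lay above 96.4% of random lists. For all 8 family lists the random lists had negative medians, from -0.43 to -0.14. The random sequences lay outside the families, so the percentiles cannot tell the function of a list from a difference between microRNAs and other sequences.

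Of the 3 families that target the RNA silencing machinery, 1 rose and 2 did neither. The Argonaute regulator miR403 rose, whereas miR168, which targets another Argonaute gene, had a ratio of 0.817 (0.798 to 0.835) and miR162, which targets a Dicer-like gene, the ratio of 0.570 given above, neither of which passed 2-fold. The list's median log2 ratio was -0.29, above 59.3% of random lists, and turned to 0.07 when scaled to the median sequence. In the copper and oxidative stress list, miR408 rose and miR398, which targets superoxide dismutase genes, was at 0.585. The log2 ratio of miR398 turned positive over distinct sequences (0.41), and also under the read minimum when no substitution was allowed (2.54) or only sequences equal to a reference over its first 20 bases counted (2.22). Its median over the 2 measured members of 3 was 0.52, above 92.0% of random lists. The phosphate and sulfate nutrition list had 1 measured member of 3, miR395, which fell (median -1.15, above 8.3% of random lists). The phase change list also had 1 measured member, miR156/miR157 at a log2 ratio of 0.24, above 64.0% of random lists, with miR172 under the minimum.

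Among the 5 families of auxin signalling, 4 were measured and none passed 2-fold scaled to all reads. The family miR390 did pass it scaled to the median sequence (log2 ratio 1.27) and when only sequences equal to a reference over its first 20 bases counted (1.22). Besides miR167 and miR390 the measured members were miR160, with a ratio of 1.19 (0.876 to 1.62), and the trans-acting small RNA tasiARF. The latter, which targets auxin response factor genes, had a ratio of 1.12 (0.803 to 1.56). The intervals of miR160 and tasiARF included 1, so a difference was not detectable at 174 and 151 reads. The median log2 ratio of the list was 0.21, above 89.6% of random lists.

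The next comparison concerned the lengths of the small RNAs, which separate 21-nt and 22-nt classes rich in microRNAs from the 24-nt class typical of heterochromatic small interfering RNAs in plants. Small RNAs of 24 nt made up 15.995% of reads in mature seed and 21.6% in germinating seed. Those of 21 nt made up 43.8% and 41.0%, and those of 22 nt 20.0% and 18.7%. The ratio of 24-nt to 21-nt reads was 0.365 (0.364 to 0.367) in mature seed and 0.527 (0.525 to 0.529) in germinating seed, 1.44 times higher. By distinct sequences the ratio was 2.33 and 2.35. Without the sequences read once it was 0.152 and 0.160, so the difference depended on sequences with 1 read. These held 19.6% of all reads in mature and 31.2% in germinating seed. They held 61.9% and 74.3% of the 24-nt reads, and 8.16% and 15.4% of the 21-nt reads.

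**Figure D2:**
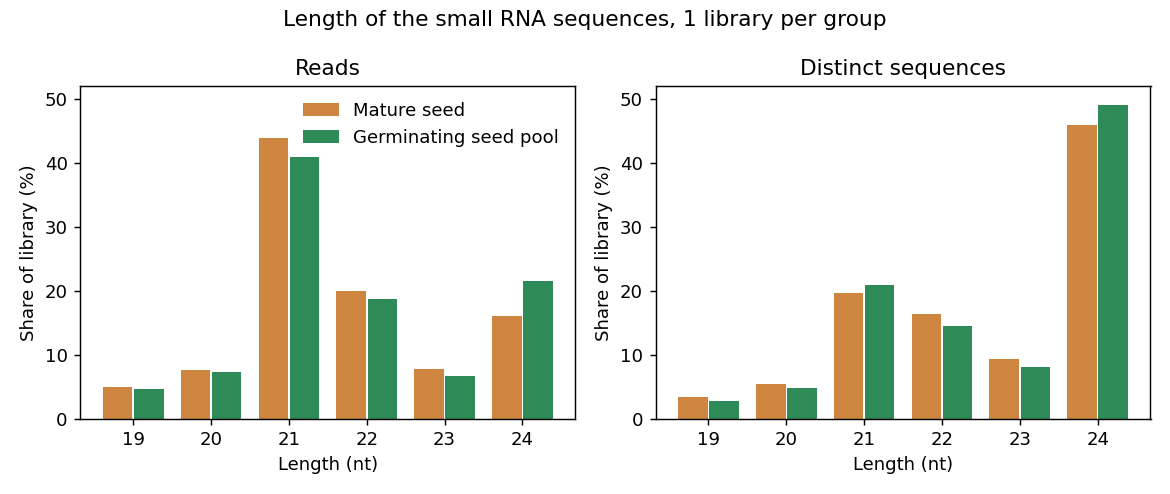
Share of each library in percent (y axes) by length in nt (x axes), for reads on the left and distinct sequences on the right, 1 library per group; brown bars are mature seed and green bars the germinating seed pool. Reads peak at 21 nt with 43.8% and 41.0%, whereas distinct sequences peak at 24 nt with 45.9% and 49.0%.

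The first base of the small RNAs, which in plants goes with the Argonaute protein that binds them, was U in 63.1% of 21-nt reads of mature seed (63.0 to 63.2%) and in 61.5% of those of germinating seed (61.4 to 61.5%). Over distinct 21-nt sequences the order turned, with 46.9% and 48.5%. Among 24-nt reads, A was the first base in 34.8% (34.6 to 34.9%) in mature and 40.7% (40.6 to 40.9%) in germinating seed, and U in 31.9% and 28.3%. Among 22-nt reads U led with 49.5% and 51.1%.

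The libraries shared 127552 distinct sequences, which were 18.02% of the distinct sequences of mature seed and 13.9% of those of germinating seed. Without sequences read once the order of the libraries turned, with 44.9% and 47.7%. All shared sequences together held 77.1% and 67.6% of the reads. Sharing was greater among 21-nt small RNAs, where shared sequences held 88.9% of mature seed reads and 83.9% of germinating seed reads, than among 24-nt small RNAs, where they held 38.2% and 22.9%.

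The ends of the microRNAs, as a sign of trimming, tailing or RNA quality, were close in both libraries. The reference 5′ end was kept by 88.1% of microRNA reads in mature seed (88.0 to 88.2%) and 85.8% in germinating seed (85.7 to 85.9%). With no substitution allowed it was kept by 94.5% and 92.9%, so these shares depend on the matching to the reference list as well as on the reads. At the 3′ end 2.94% and 2.99% of reads were shorter than the reference, and 11.1% and 11.3% were longer. Of 11 animal microRNAs listed as a sign of RNA from other organisms, 2 reads were found in mature and 1 in germinating seed.

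Outside the microRNA families, the most abundant sequence of both libraries was TGAATCTCAGTGGATCGTGGC, antisense to the 3′ region of 25S ribosomal RNA, with 104140 reads in mature and 56741 in germinating seed (1.57-fold lower in germinating seed, interval 1.56 to 1.59). The unnamed 22-nt sequence AGTTACTAATTCATGATCTGAC came next in each, with 36069 and 55680 reads (ratio 1.80, 1.78 to 1.82), and its 23-nt form AGTTACTAATTCATGATCTGACA had a ratio of 1.60. Scaled to the median sequence, the 22-nt form had a log2 ratio of 1.21 and so passed 2-fold. The 19-nt fragment GACCGCATAGCGCAGTGGA, from the 5′ end of an arginine transfer RNA, rose 5.83-fold (5.65 to 6.01), from 4858 to 24301 reads. The remaining leading sequences were sense fragments of the 25S 3′ end. Of these AGCCCTTGTCGCTTTGATTCGT fell, 2.39-fold lower in germinating seed (2.33 to 2.45), though its log2 ratio of -0.89 relative to the median sequence was under 2-fold. The longer forms CAGCCCTTGTCGCTTTGATTCGT and TCAGCCCTTGTCGCTTTGATTCGT were 1.60-fold and 1.78-fold lower.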

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

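The sequences in this part were chosen after their values were seen, the other hairpin arms for a ratio at least 2-fold above their guide's. Each is a signal outside the microRNA families that exceeded the limit a count of 0 allows, as many other sequences did. The 3 tests on arginine transfer RNA fragments were chosen after the data or the results were seen, as was the test of the 24-nt ratio without ribosomal and transfer RNA fragments. The 24-nt ratio without leading sequences was an alternative fixed before the data were examined. It was taken as a test of that pattern only after its value was seen.

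Fragments of 19 nt from the 5′ ends of arginine transfer RNAs rose from 5570 reads in mature seed to 28644 in germinating seed, 5.99-fold (5.82 to 6.17). Selection of 19-nt RNA in the germinating library would raise other 19-nt sequences too, but their median log2 ratio was -0.81. General breakdown of these transfer RNAs would raise the 20 to 24 nt fragments from the same ends. The log2 ratio of those fragments was -0.47 (-0.58 to -0.37), or -0.11 relative to the median sequence, so they were not higher on either scale. Amplification of 1 molecule would not raise all 3 arginine sequences of 19 nt (GACCGCATAGCGCAGTGGA 5.83-fold, GACTCCATGGCCCAATGGA 7.39-fold and GCGCCTGTAGCTCAGTGGA 6.66-fold), although these were grouped after their values were seen and the first held 24301 of the 28644 reads. Fragments of 19 nt from 16 other transfer RNA ends had a log2 ratio of -0.50 in sum, or -0.13 relative to the median sequence. Those of 20 to 24 nt had -1.31, or -0.95 relative to the median sequence. The histidine 19-nt fragment, under the 50-read minimum, had 5 and 18 reads (ratio 4.20, 1.501 to 14.5). A candidate explanation, as a hypothesis drawn from the same data and not itself tested, is cleavage at a fixed place in arginine transfer RNAs in germinating seed. These libraries without replicates cannot establish it.

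Fragments from the interior of a 269-nt stretch joined from reads, assigned to 25S ribosomal RNA from general knowledge, rose steeply in germinating seed: CGGTGGACTGCTCGAGCTGC from 70 to 11171 reads (186-fold, 147 to 239), GCCGGTCGGGGGACGGATTGGGA from 412 to 9897 (28-fold, 25.4 to 31.0) and CCCAGTCCCGAACCCGTCGGC from 156 to 2122 (15.9-fold, 13.5 to 18.8). General breakdown of 25S RNA would raise the stretch at large, but its other 765 sequences had a median log2 ratio of -0.84 (-0.90 to -0.78). Their reads in sum, 50527 in mature and 39167 in germinating seed, differed less, with a ratio of 0.904 (0.892 to 0.916). The 64 of these within 2 nt of a leading position had a median of 0.30 (-0.32 to 1.22) and a ratio of 3.31 in sum. The other 701 had a median of -0.87 and a ratio of 0.588 in sum. Selection of RNA by size would raise other sequences of the same lengths, but their median was -0.34. Ribosomal RNA of another organism in the germinating pool could not be excluded: 100% of the 16-base words of the stretch occurred in mature seed reads, but an organism with the same sequence would give the same result. Site-specific cleavage in germinating seed stays open as a hypothesis beside it and was not tested.

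The higher ratio of 24-nt to 21-nt reads in germinating seed, 1.44 times that of mature seed, was weighed against 3 technical explanations. A few abundant sequences would not explain it, since the ratio of ratios was 1.48 without the 10 leading sequences of each library, nor would the lower share of ribosomal and transfer RNA fragments, since it was 1.45 without those listed. The test of sequencing depth could not decide: over distinct sequences the ratio of ratios was 1.01 before and 1.03 after thinning to equal depth. That quantity did not show the pattern and cannot speak on its cause, although a value above 1 had been set as evidence against depth. The pattern is one of reads, and thinning a library at random leaves the expected ratio of 24-nt to 21-nt reads unchanged. Random sampling to a different depth would therefore not by itself be expected to give it. Leaving out sequences with 1 read lowered the ratio of ratios to 1.06, so the pattern depends on sequences read once. These were not more numerous at 24 nt alone. At 24 nt they numbered 300522 in mature and 417234 in germinating seed, or 61.9% and 74.3% of reads of that length. At 21 nt they numbered 108476 and 163799, or 8.16% and 15.4%. Whether some of these hold sequencing errors, and whether germination itself changed the 24-nt class, was not tested.

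Reads antisense to the 25S 3′ region numbered 178346 in mature seed and 116245 in germinating seed. The unnamed sequence AGTTACTAATTCATGATCTGAC had 55680 reads in germinating seed. The other hairpin arm of miR159 had 450 reads in germinating seed against 87 in mature seed, that of miR165/miR166 had 3093 against 836, and that of miR319 had 64 against 14.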

How the results depend on the processing

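The alternatives that left out the ribosomal and transfer RNA lists, or the leading sequence of each family, were chosen after seeing the data. The 8 called families gave 79 values over 11 alternatives, all in the main direction and 63 within their main interval. A change of the minimum number of reads cannot move a ratio, so the values from those alternatives equal the main ones and add no support. Families under the minimum in an alternative gave no value there. Where values moved, the cause was not tested unless given here. The 6 families that rose became 2 with a minimum of 500 reads, which removed families with fewer reads, and 0 over distinct sequences, where all 6 ratios were smaller, 4 with intervals that included 1 (miR403 dropped from a log2 of 2.81 to 1.09) and those of miR171 and miR396 under 2-fold. The 2 that fell became 0 over distinct sequences and 0 with median-of-ratios scaling, which moved every log2 ratio up by one amount. With the leading sequence of each family left out, 4 families rose, of which 2 were among the main 6. List medians moved with the scaling. Scaled to microRNA reads they were 0.30 (development), -0.25 (silencing), 0.28 (phase change) and 0.51 (other legume). With median-of-ratios scaling they were 0.63 (development), -0.78 (phosphate and sulfate), 0.61 (phase change), 0.68 (disease resistance) and 0.83 (other legume), while silencing reversed from -0.29 to 0.0716. Scaled to reads outside the ribosomal and transfer RNA lists they were 0.16 (development), -0.40 (silencing), 0.14 (phase change) and 0.21 (disease resistance). In mature and germinating seed in turn, the microRNA share was 19.5% and 18.7% with 0 substitutions, 21.4% and 20.8% with 2, 22.3% and 21.6% of reads of 20 to 24 nt, 26.4% and 30.0% without sequences read once, and 26.6% and 23.97% without the ribosomal and transfer RNA lists. The ratio of 24-nt to 21-nt reads was 0.152 and 0.160 without sequences read once, 0.540 and 0.798 without 10 leading sequences, 2.33 and 2.35 over distinct sequences, and 0.415 and 0.604 without the ribosomal and transfer RNA lists. Shared sequences were 44.9% and 47.7% of distinct sequences without those read once, and 19.1% and 13.0% with mature seed thinned to equal depth. Over distinct sequences, a first base U in 21-nt RNA had shares of 46.9% and 48.5%, and A in 24-nt RNA 37.2% and 42.1%. With 0 substitutions the microRNA 5′ end was kept by 94.5% and 92.9%. Depth limited 9 families, which had under 50 reads. No paired analysis was possible because each group had 1 library, and for the same reason no replicate could be left out. Alternatives for genome matches, annotation classes, hairpin candidates and annotated structural RNA were not run, since no genome sequence was used here.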

Other observations

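The list of other hairpin arms was written after the data had been examined, and the values in this part were chosen after they were seen.

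The other arms of microRNA hairpins, the strand usually discarded when the guide strand is loaded, rose in germinating seed for miR159, miR165/miR166, miR319, miR396 and miR1510. The arm of miR159 rose 6.03-fold (4.78 to 7.67, from 87 to 450 reads) while its guide had a ratio of 0.861, and that of miR319 rose 5.33-fold (2.96 to 10.3, from 14 to 64 reads) beside a guide ratio of 0.798. The arm of miR165/miR166 rose 4.31-fold (3.99 to 4.66) beside a guide ratio of 1.10, so that there were 1.12 arm reads per 100 guide reads in mature seed and 4.39 in germinating seed. The arm of miR396 rose 4.22-fold (3.96 to 4.50) beside a guide that rose 3.21-fold, and that of miR1510 rose 2.76-fold (2.66 to 2.87) beside a guide ratio of 1.98. Arm reads outnumbered guide reads for miR396, with 133 and 175 per 100, and for miR1510, with 183 and 255 per 100. They also did for miR172, with 26 and 25 arm reads, but its guide, with 5 and 17 reads, was under the minimum. The miR172 arm had a ratio of 1.12 (0.621 to 2.02) beside a guide ratio of 3.96. Of 10 arms with at least 50 reads for the arm and also for its guide, 8 had a higher ratio than their guide. No scaling of the libraries alters this comparison, but only the arms of miR159, miR319 and miR165/miR166 were at least 2-fold higher relative to their guides. The median log2 ratio of arm relative to guide was 0.44, and the interval of the miR169 arm (-0.12 to 1.29) included its guide's 0.29. The exceptions were miR171, with 15.8 arm reads per 100 guide reads in mature seed and 11.05 in germinating seed, where the arm's interval (0.14 to 1.19) included its guide's 1.18, and miR482/miR2118, with 87.6 and 47.5.

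Ribosomal RNA fragments made up less of germinating seed reads on each of the sense strands listed. For 25S RNA the list held only the 3′ region, and the leading fragments of the 269-nt stretch described above went the other way. The 5.8S fragments had 3.92% of reads in mature seed and 2.03% in germinating seed, the 5S fragments 0.389% and 0.263%, and sense fragments of the 25S 3′ region 7.64% and 4.91%. Antisense reads of the 25S 3′ region had 5.88% and 4.46%, and the single sequence TGAATCTCAGTGGATCGTGGC held 104140 of the 178346 antisense reads in mature seed and 56741 of 116245 in germinating seed. They were mostly of 21 nt, at 91.0% and 88.8% of these reads, against 44.8% and 51.7% of the sense reads. Antisense reads of 5.8S were rarer, at 0.0297% and 0.0264%. Antisense reads of 5S went the other way, with 51 reads in mature and 84 in germinating seed (ratio 1.92), a log2 ratio of 0.94 that became 1.30 relative to the median sequence.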
